A study of Mus musculus with 4 samples.

How the data were processed

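Cells of the mouse submandibular gland, depleted of EpCAM and Ter119 cells with magnetic beads and of dead cells, were captured with 10x Genomics droplets, per the labels' protocols, which also say that submandibular and sublingual glands were harvested. The deposited values are counts, that is raw UMI counts per gene and barcode after the authors' calling of cell barcodes, in 1 sparse matrix per library, with no normalization. Per the submitters' processing notes, Cell Ranger 7.0.1 and the mm10 build were used. Per the file headers, the matrices came from Cell Ranger 6.0.1 (ligated and mock 1) and 7.0.0 (mock 2 and mock 3), and this difference was not resolved. By its published defaults Cell Ranger counts intronic reads from version 7 on and not before, and whether introns were counted here is not given in the sources used here. The feature lists held 32285 genes in the ligated library, 31053 in mock 1 and 32287 in mock 2 and 3, the latter including CreERT2 and tdTomato, both at 0 UMIs. Genes were joined by ID, and the 30406 IDs in all 4 lists were used. IDs outside them held 0.456, 0.054, 0.449 and 0.451% of the UMIs of the ligated library and mock 1, 2 and 3.

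Before the data were examined, the groups, tests, gene lists, cell type markers, the rule for named genes and the alternatives were fixed. Cells were kept with at least 500 UMIs, at least 300 genes and at most 15% of UMIs from mitochondrially encoded genes. Doublets were called per library with Scrublet, as built into scanpy 1.11.5, and removed. It called 742 barcodes (5.38%) in the ligated library, 71 (1.48%) in mock 1, 0 in mock 2 and 1 in mock 3, so that in 2 libraries the caller had not worked and doublets remain there. As an alternative chosen after seeing this, the highest-scoring barcodes, 0.8% per 1000 barcodes, were removed in each library. Counts were scaled per cell and log-transformed, 2000 variable genes were chosen with the library as batch, and 30 principal components and the 15 nearest neighbours gave a graph weighted by shared neighbours. Clusters came from the Leiden method (leidenalg 0.10.2, igraph 0.11.9) at a resolution of 1.0, with no batch integration, in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0 and pandas 2.3.3.

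A cluster was named for the class whose fixed markers had the highest mean log2 ratio of their CPM to the median CPM over all clusters (10 CPM added to each). A name needed at least 3 of its markers with a UMI in at least 25% of the cluster's cells, a mean of at least 0.5 and no more markers of other classes than of its own among the 10 leading genes. A class that alone led those 10 genes with at least 3 markers was preferred where its mean was at least 2.0. Clusters led by cell cycle genes, or low in UMIs, with no marker of their class among those 10 stayed unnamed. Clusters with more than 2.0 times the median UMIs and a second class at 1.5 or more were left unnamed as possible doublets. This scoring was set after the clusters were seen, because an earlier one, based on leading genes alone, left the largest endothelial clusters unnamed. Endothelial cells were clustered again at a resolution of 1.0, giving 17 sub-clusters, with 2.0 and 0.5 as alternatives. The check of leading genes for sub-cluster names was likewise added after the names were seen, and shares without it are given too. B-like, dendritic-like, lymphatic endothelial-like, glia-like and the remaining classes had under 30 cells in some library, or were not among the classes planned for a test, and were not tested.

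Shares of cells are given for the ligated library with the exact (Clopper-Pearson) binomial 95% interval and for the 3 mock libraries as mean and SD. For each tested class the raw counts were summed per library and compared with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test, with TMM normalization, filterByExpr and Benjamini-Hochberg adjustment at 0.05 over the genes of the class. With 1 ligated library the spread comes from the mock libraries, with 2 residual degrees of freedom, and the ligated library is assumed to vary like them. Fold changes are given with their standard errors, and CPM per library are scaled by the TMM library size. Gene lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and with fry, whose p tests whether a list moves on balance in 1 direction. No list passed in any class with an estimated correlation or with fry. Both rest on the 2 residual degrees of freedom, so a pass was hard to reach and a failure is weak evidence against a list. Counts adjusted over the list alone repeat the adjustment over the list's members. Where a list is said to turn direction, the direction is camera's, which sets its members against the other genes. It can turn while the list's own median keeps its sign. A class by surgery term, in a fit with a term for each library, compared the difference between fibroblasts and endothelial cells in the ligated library with that in the mock libraries.

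Named genes were, per class, the 12 largest changes up and down among genes past the threshold with a mean log2 CPM of at least 5, outside the mock range and not markers of another class. Where fewer than 5 genes passed, which was the case in every class, the 5 of smallest p were named instead. Up to 4 members of smallest p of each list that passed were added. A gene whose CPM in another class of the same libraries was over 20 times that in the class is called out-of-class. Intron lengths and coordinates (1-based) came from GENCODE M21 for mm10.

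The edgeR step was tested on simulated data with 200 changed genes per class, drawn from the real means and library sizes. It recovered 7% of 2-fold and 43% of 4-fold changes in endothelial cells (14157 genes), 7 and 46% in fibroblasts (12477), and 8 and 42% in macrophages or monocytes (10384). In mural cells it recovered 0 and 45% (11543), in T cells 7 and 68% (10449) and in NK or ILC1 cells 3 and 49% (12220). A 2-fold change in the ligated library is therefore mostly below what this design detects. In the real libraries 0 of 12477 fibroblast genes passed, although Mgp and Postn stood over 4-fold above the mock mean. The simulated shares may thus overstate what is detected in the real libraries. A count of 0 does not show that few genes changed.

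Alternatives fixed before the data were examined were DESeq2 1.42.0 and its size factors in edgeR, no filter on low counts, edgeR's robust fit, sums thinned to the smallest library, and out-of-class genes left out. They also covered a looser cell filter (200 genes, 25% mitochondrial, no UMI minimum), a stricter one (1000 UMIs, 5%), doublets kept, each library clustered on its own, a resolution of 2.0, and each mock library left out. Chosen after seeing the data were the Cell Ranger version as a term, genes with at most 10 kb of intron, doublets by score rank, the interaction without out-of-class genes and with a class by version term, the naming of sub-clusters by score alone, and list medians within single clusters. The last were taken as differences of log2 of CPM plus 1, between the ligated library and the mean of the mock libraries, in T cell and macrophage clusters with at least 30 cells in every library. Figures were drawn with matplotlib 3.10.9.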

Results

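Single-cell RNA sequencing was done on the submandibular salivary gland of female C57BL6/J mice, enriched for stroma by removing cells that carry EpCAM, a surface protein of epithelium, or Ter119, a surface protein of red blood cells. Tissue was taken 14 days after a metal clip closed the main ducts (ligated) or after mock surgery that left the ducts open. The comparison asks how stromal and immune cells of the gland differ after 14 days of duct obstruction. There was 1 ligated library and there were 3 mock libraries, called mock 1, 2 and 3. The ligated library held 13790 cell barcodes and 80187555 unique molecular identifiers (UMIs, each standing for 1 captured transcript), at a median of 4617 UMIs and 1838 genes per barcode. Mock 1 held 4798 barcodes and 29897488 UMIs at medians of 5413.5 and 2136.5. Mock 2 held 9627 barcodes and 47182114 UMIs at medians of 4096 and 1925, and mock 3 held 13194 barcodes and 56932041 UMIs at medians of 3507.5 and 1683.5. After filtering, 12576, 4520, 9251 and 12698 cells were analysed.

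The libraries differed in processing in more than 1 way. The file headers name Cell Ranger 6.0.1 for the ligated library and mock 1, and 7.0.0 for mock 2 and mock 3. In endothelial cells, genes with over 100 kb of intron had a median log2 ratio of mock 2 and 3 over mock 1 of 0.43 (713 genes), against -0.03 for genes with up to 1 kb (368 genes). The corresponding medians of the ligated library over mock 1 were -0.00 and -0.01. Medians of the ligated library over mock 1, which share a version but not a feature list, are therefore given for the lists that passed. For some of the genes log2 ratios are given. They compare 1 library with 1 and have no test, and for the other genes only pooled values are given. Summed counts of mock 2 and mock 3 differed by a chi-square of 5.33 per degree of freedom, against 93.1 to 137 for every other pair of libraries. No label says whether each library came from a separate animal, and mock 2 and mock 3 may not. P-values of single genes therefore measure only the spread between these samples, which may be technical. Camera p-values at the preset correlation of 0.01 compare list members with the other genes, taken as nearly independent. They do not measure the spread between libraries. Camera with an estimated correlation and fry take that spread from 2 residual degrees of freedom. A list that did not pass them may therefore still differ. If mock 2 and mock 3 are not separate animals, n = 3 overstates the number of animals, the SDs understate the spread between them and the p-values are too small. This holds most for fits that take the spread from mock 2 against mock 3 alone, as those without mock 1 or with a version term do. With a version term the estimate itself rests on the ligated library against mock 1 alone. Such values and the ratios over mock 1 are therefore 1 comparison and not 2 separate checks.

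Clustering gave 37 clusters, of which 30 took a cell class from markers fixed before the data were examined and 7 stayed unnamed. Endothelial-like cells, carrying markers such as Pecam1 and Cdh5, numbered 4138 in the ligated library and 2665, 5055 and 6791 in mock 1, 2 and 3. Fibroblast-like cells numbered 1212 against 207, 424 and 576, and mural-like cells, the contractile cells of vessel walls, 570 against 267, 334 and 483. NK- or ILC1-like lymphocytes numbered 3272 against 650, 974 and 1459, T-like cells 1445 against 158, 254 and 350, and macrophage- or monocyte-like cells 633 against 74, 298 and 388. These 6 classes had at least 30 cells in every library and were tested. In endothelial cells, fibroblasts, mural cells, NK or ILC1 cells and macrophages or monocytes, the cluster that held the most cells of the class was not the same in every library. Of the ligated fibroblasts, 1171 lay in a cluster led by Spp1, Cilp, Thbs4, Mgp and Timp1 that held 70, 35 and 57 mock cells. A fibroblast cluster led by Lsamp, Fgf10 and Lama2 held 19 ligated and 125, 383 and 512 mock cells. Among endothelial cells, a cluster led by Aqp1 and Inhbb held 2458 ligated and 377, 54 and 51 mock cells. Another led by Car4 and Tcf15 held 67 ligated and 296, 2481 and 3466 mock cells, and a cluster led by Cdkn1a and Sgk1, held 151 ligated, 1234 mock 1, 78 mock 2 and 94 mock 3 cells. Of the NK or ILC1 cells, a cluster led by Gzmc held 2957, 472, 5 and 30 cells and one led by Clnk held 4, 10, 962 and 1407, so that these 2 clusters parted the libraries by software version.

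Fibroblasts, T cells, NK or ILC1 cells and glia made up a larger share of the ligated library than of any mock library, and endothelial cells a smaller one. Endothelial cells were 32.9% of ligated cells (exact binomial 95% interval 32.1 to 33.7%) and 55.7% ± 2.89 of mock cells (SD, n = 3). Fibroblasts, which make the collagenous matrix, were 9.64% (9.13 to 10.2%) against 4.57% ± 0.0262. Glia, the cells that wrap peripheral axons, were 2.46% (2.19 to 2.74%) against 0.462% ± 0.0549. NK or ILC1 cells were 26.0% (25.3 to 26.8%) against 12.1% ± 2.00, T cells 11.5% (10.9 to 12.1%) against 3.00% ± 0.430, and macrophages or monocytes 5.03% (4.66 to 5.43%) against 2.64% ± 0.871. The share of mural cells, 4.53% (4.17 to 4.91%), lay within the mock range of 3.61 to 5.91%. Against mock 1 alone, the ratio of shares was 0.558 for endothelial cells, 2.10 for fibroblasts, 4.83 for glia, 1.81 for NK or ILC1 cells, 3.29 for T cells and 3.07 for macrophages or monocytes. A single library against 3 cannot give an exact permutation p under 0.25, so the shares carry no test, and the intervals cover counting error only.

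**Figure D1:**
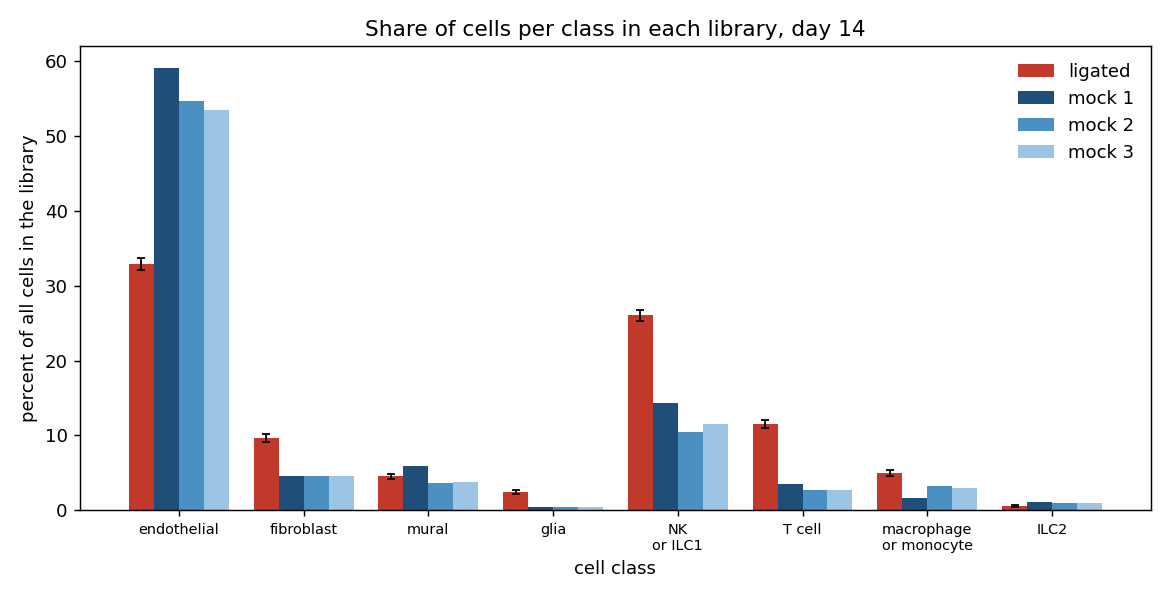
Percent of all cells of a library (vertical axis) that fell in each of 8 cell classes (horizontal axis), with 1 bar per library and, on the ligated bar, the exact binomial 95% interval. Endothelial cells are 32.9% of the ligated library and 53.5 to 59.0% of the mock libraries, and fibroblasts are 9.64% against 4.54 to 4.58%.

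Because the depletion acts on epithelial and red cells, shares were also taken within the non-immune stromal cells and within the immune cells. Fibroblasts were 19.4% of the stromal cells of the ligated library (18.4 to 20.4%) and 7.01% ± 0.418 of those of the mock libraries (n = 3). Glia were 4.94% (4.41 to 5.50%) against 0.707% ± 0.0551, endothelial cells 66.1% (64.9 to 67.3%) against 85.4% ± 1.11, and mural cells 9.11% (8.40 to 9.84%) against 6.74% ± 1.47. Within the immune cells, T cells were 26.6% (25.4 to 27.8%) against 15.8% ± 0.901, whereas NK or ILC1 cells, at 60.1% (58.8 to 61.4%), lay within the mock range of 59.6 to 69.0%. So did macrophages or monocytes, at 11.6% (10.8 to 12.5%) and a range of 7.86 to 18.2%. Group 2 innate lymphoid cells (ILC2), which bear the interleukin 33 receptor Il1rl1, were 1.43% (1.13 to 1.79%) against 5.29% ± 0.196. Epithelial cells left after depletion were 2.83% of all ligated cells against 6.56% ± 1.30, and erythroid cells 0.366% against 1.65% ± 0.142. Unnamed clusters held 3.76% of ligated cells and 2.19, 9.87 and 10.6% of mock 1, 2 and 3. Scrublet called doublets in 5.38% of ligated and 1.48% of mock 1 barcodes but in 0 of mock 2 and 0.00758% of mock 3, where the caller had not worked.

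Fibroblasts of the ligated library carried more transcripts of interstitial matrix than those of every mock library. Mgp (ENSMUSG00000030218, chromosome 6, 136872435 to 136875823, mm10), which encodes matrix Gla protein, an inhibitor of calcification, stood at 31932 CPM (counts scaled to a common library size) against 6840 ± 326 (SD, n = 3), a log2 fold change of 2.22 ± 0.11 (SE). Of the list of fibrillar and interstitial matrix genes, 18 of 25 members lay above and 1 below the mock range, with a median log2 fold change of 0.94. Col8a1 (ENSMUSG00000068196, chromosome 16, 57624258 to 57754737), a short-chain collagen, stood at 505 CPM against 28.4 ± 14.4, and Postn (ENSMUSG00000027750, chromosome 3, 54361109 to 54391037), which encodes the matricellular protein periostin, at 642 against 101 ± 41.4. Col1a1, the main chain of type I collagen, stood at 4368 against 2153 ± 408, and Thbs2, a matricellular thrombospondin, at 154 against 69.7 ± 12.7. Basement membrane genes lay lower, with 10 of 14 members below and 1 above the mock range and a median of -0.45. They included Nid2 (90.8 against 223 ± 19.4 CPM), which links laminin to collagen IV, the laminin chains Lamb1 (434 against 682 ± 27.8) and Lamc1 (263 against 462 ± 65.9), and the proteoglycan perlecan, Hspg2 (548 against 831 ± 55.6).

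By edgeR's quasi-likelihood test 0 of 12477 genes in fibroblasts passed an adjusted p of 0.05, and the adjusted p of Mgp, the smallest, was 0.122. At an unadjusted p under 0.05 there were 1522 genes, and DESeq2 called 282. With the Cell Ranger version as a term, which leaves 1 residual degree of freedom and takes the spread from mock 2 against mock 3, 3306 genes passed, without mock 1 7052 did and without the low count filter 23. The matrix list passed the camera test (adjusted p = 4.2e-07, and adjusted p = 0.683 with an estimated correlation), and adjusted over the list alone 4 members rose and 1 fell. Its median over mock 1 alone was 0.36 and with the version term, which rests on the same comparison, 0.39. The log2 ratios of Mgp, Col8a1 and Postn over mock 1 were 2.15, 3.46 and 2.12. The basement membrane list also passed (adjusted p = 0.0191, and adjusted p = 0.683 with an estimated correlation), with 1 member down adjusted over the list alone and a median over mock 1 of -0.57.

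Protease inhibitors and members of the TGF-beta response also stood high in ligated fibroblasts. Timp1 (ENSMUSG00000001131, chromosome X, 20870166 to 20874735), an inhibitor of matrix metalloproteinases, was at 848 CPM against 60.2 ± 56.7, a mean that mock 1 raised with 126 CPM. Serpine2, a thrombin and plasmin inhibitor, was at 386 against 139 ± 21.5, and Ctsk, the collagen-degrading cathepsin K, at 541 against 274 ± 26.1. Ltbp2, a protein of elastic fibres, was at 201 against 7.42, 0 and 0.505 in mock 1, 2 and 3, Tgfb1, the cytokine itself, at 135 against 64.4, 23.6 and 25.5 in mock 1, 2 and 3, and Smad7, an inhibitor of its signalling, at 59.6 against 38.2 ± 0.941. The protease and inhibitor list (median 0.32, 9 of 17 members above the mock range, adjusted p = 0.00326, 5 up adjusted over the list alone) and the TGF-beta list (median 0.73, 9 of 17 above, adjusted p = 0.000807, 2 up adjusted over the list alone) passed camera. For each, the adjusted p was 0.683 with an estimated correlation. With the version term camera's direction for the protease list turned, far from the threshold, while the list's own median stayed positive at 0.16. The medians over mock 1 were 0.16 for proteases and 0.60 for the TGF-beta list.

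Il34 (ENSMUSG00000031750, chromosome 8, 110741829 to 110805924), a ligand of the macrophage growth factor receptor Csf1r, stood at 238 CPM in ligated fibroblasts against 40.0 ± 2.95. Interferon-stimulated genes lay above the mock range in 20 of 25 members, with a median log2 fold change of 0.40. They included Cxcl9, a chemokine induced by interferon gamma, at 83.7 against 4.71 ± 3.31 and the nucleic acid sensor Zbp1 at 27.9 against 11.8 ± 0.789. Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), which encodes osteopontin and is on the list of lipid-associated macrophage genes, stood at 3595 against 86.7 ± 39.7. Bpgm, an enzyme abundant in red cells and a leading gene of the erythroid cluster, stood at 149 against 10.4 ± 2.43. The interferon list (adjusted p = 1.9e-05, 1 up adjusted over the list alone) and the lipid-associated macrophage list (median 0.39, adjusted p = 0.00417, 4 up adjusted over the list alone) passed camera, as did ribosomal proteins (median 0.32, adjusted p = 0.00205), heat shock (median 0.54, adjusted p = 0.00675) and cell cycle genes (median 0.51, adjusted p = 0.0191). The last 3 had 0 members passing adjusted over the list alone, with edgeR, and each of the 5 lists had an adjusted p of 0.683 with an estimated correlation. Heat shock (adjusted p = 0.270) and cell cycle (adjusted p = 0.0735) did not pass with the version term, and cell cycle did not pass without mock 1 (adjusted p = 0.0837) or mock 2 (adjusted p = 0.0614). The medians over mock 1 were 0.55 for interferon, 0.22 for lipid-associated macrophage, 0.23 for ribosomal, 0.24 for heat shock and 0.40 for cell cycle genes.

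Transcripts that other classes carry at over 20 times the level, here called out-of-class, moved with several fibroblast lists. All 6 members of the MHC class II list (median 2.14, adjusted p = 0.000398, 3 up adjusted over the list alone) were of this kind, including H2-Ab1 at 48.5 CPM against 10.4 ± 4.26 and Cd74 at 163 against 32.3 ± 21.6. So were 9 of 11 T effector genes (median 1.54, adjusted p = 1.9e-05, 0 adjusted over the list alone). Of 12 complement genes (median 0.32, adjusted p = 0.00892, 3 up and 1 down adjusted over the list alone), 4 were of this kind. Among these were C1qb at 57.9 against 6.19 ± 0.630 and C1qa at 58.5 against 7.23 ± 0.582, subunits of complement C1q made by macrophages, and the other 8 members had a median of 0.07. Capillary and fatty acid handling genes lay lower (median -1.25, adjusted p = 0.000807, 3 down adjusted over the list alone). Of its 15 members 9 were out-of-class, Fabp4 at 94.8 against 404 ± 187 among them, and the others had a median of -0.45. Pparg, the nuclear receptor of fat cell differentiation, was not, at 0.978 against 12.4 ± 5.16. Each of these 4 lists had an adjusted p of 0.683 with an estimated correlation. Over mock 1 the medians were 3.12 for MHC class II, 1.92 for T effector, 0.43 for complement and -0.58 for capillary genes. The complement list did not pass without mock 1 (adjusted p = 0.0752) or with the version term (adjusted p = 0.175). The other 22 fibroblast lists, among them contractile genes, the BMP, Wnt and hedgehog pathways and stromal growth factors, did not pass.

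Endothelial cells of the ligated library carried fewer transcripts of capillary fatty acid handling and of BMP signalling. Car4 (ENSMUSG00000000805, chromosome 11, 84957786 to 84966044), a carbonic anhydrase of the capillary surface, stood at 219 CPM against 547 ± 41.2 (SD, n = 3). Cd36 (ENSMUSG00000002944, chromosome 5, 17781690 to 17888801), a fatty acid transporter, stood at 271 against 592 ± 44.9, and Fabp4 (ENSMUSG00000062515, chromosome 3, 10204088 to 10208576), a fatty acid binding protein, at 4601 against 12440 ± 2075. Pparg stood at 17.7 against 42.1 ± 5.63. Bmp6 (ENSMUSG00000039004, chromosome 13, 38345107 to 38500302), a ligand that endothelium secretes, stood at 4.38 against 38.8 ± 10.6, Smad6, an inhibitor of BMP signalling that BMP induces, at 22.5 against 54.3 ± 6.50, and the signal transducer Smad9 at 1.22 against 6.56 ± 0.532. Of the capillary list 8 of 15 members lay below and 4 above the mock range (median -0.81), and of the BMP list 10 of 14 below and 2 above (median -0.57). Over mock 1 alone the list medians were -0.84 and -0.64, and the log2 ratios of Car4, Cd36, Fabp4 and Bmp6 were -1.19, -1.25, -1.69 and -2.36.

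The capillary list passed camera (adjusted p = 0.00887, and adjusted p = 0.621 with an estimated correlation), with 6 members down adjusted over the list alone. The BMP list passed at the same value (adjusted p = 0.00887, and adjusted p = 0.621 with an estimated correlation), with 3 down adjusted over the list alone, but not without mock 1 (adjusted p = 0.0579). By edgeR 0 of 14157 genes passed an adjusted p of 0.05, with 1275 at an unadjusted p under 0.05, and DESeq2 called 233. In endothelial cells 5203 passed with the version term and 8939 without mock 1. Set against the other 3 libraries in the same way, mock 1 gave 1236 genes at an unadjusted p under 0.05 and 9 past the adjusted threshold, and mock 2 and mock 3 gave 5 and 3 at the unadjusted level.

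**Figure D2:**
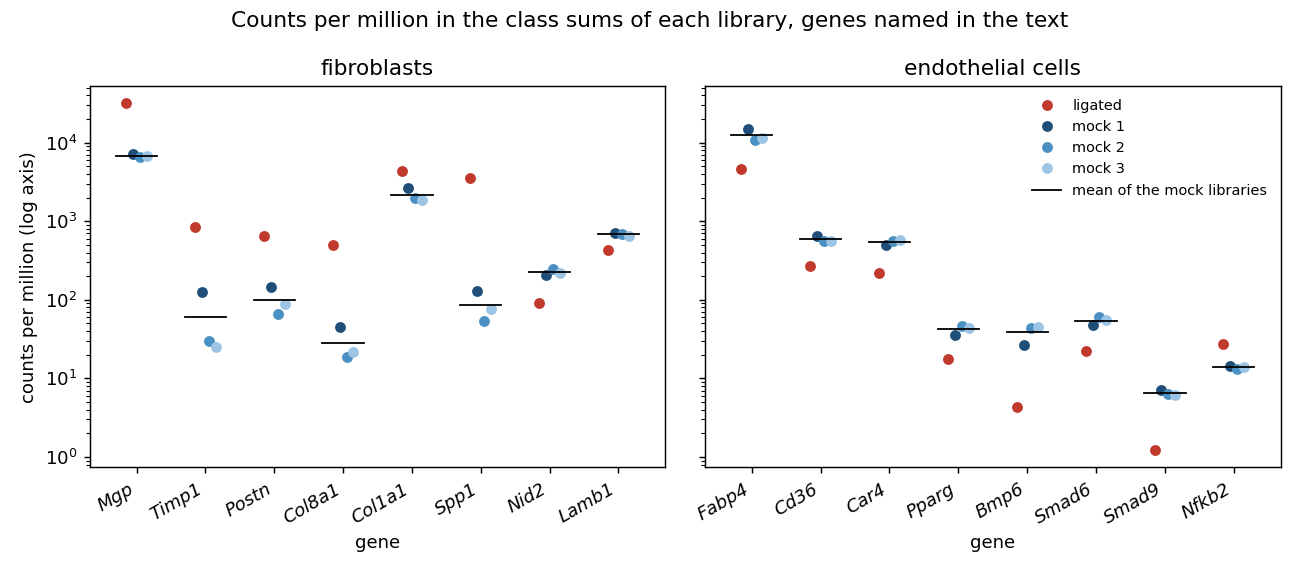
CPM (vertical axis, log scale) of 8 genes in fibroblasts (left) and 8 in endothelial cells (right), with 1 point per library and a line at the mean of the 3 mock libraries. In fibroblasts Mgp is at 31932 in the ligated library and 6530 to 7179 in the mock libraries, and in endothelial cells Fabp4 is at 4601 against 11004 to 14819.

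Cyp1a1 (ENSMUSG00000032315, chromosome 9, 57687928 to 57703824), a target of the aryl hydrocarbon receptor, had 0 UMIs in ligated endothelial cells and 11.9, 13.5 and 13.3 CPM in the mock libraries. Its adjusted p of 0.162 was the smallest of the class. Against a floor of 3 counts in the ligated library, 0.153 CPM, it was at least 84.4-fold lower. Nfkb2, a subunit of NF-kB, stood at 27.6 CPM against 13.9 ± 0.585, and mt-Co3, a mitochondrial subunit of cytochrome c oxidase, at 5917 against 3080 ± 261. The list of inflammatory cytokines and NF-kB (median 0.93, 10 of 16 members above the mock range, adjusted p = 0.000592, 5 up adjusted over the list alone) passed camera, with an adjusted p of 0.621 with an estimated correlation. Its 9 members that were not out-of-class had a median of -0.15, and it did not pass without mock 1 (adjusted p = 0.0772). Over mock 1 its median was 0.81. Mitochondrially encoded genes (median 0.32, 9 of 13 above, adjusted p = 0.0222, 0 adjusted over the list alone) also passed, but not with an estimated correlation (adjusted p = 0.791), with the version term (adjusted p = 0.120) or without mock 2 (adjusted p = 0.139), and had a median of 0.27 over mock 1.

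Out-of-class transcripts were common in the other endothelial lists that lay higher. Among the 5 genes of smallest p were C1qb at 32.7 CPM against 2.31 ± 0.162, C1qa at 39.7 against 1.87 ± 0.273, the lymphocyte chemokine Xcl1 at 28.4 against 2.23 ± 0.294 and the macrophage gene Ms4a7 at 10.4 against 0.324 ± 0.0507, all 4 of this kind. Ccl5, a chemokine of T and NK cells, stood at 152 against 7.55 ± 3.93 and Col3a1, a fibroblast collagen, at 37.6 against 1.93 ± 0.966, both also of this kind. Of this kind were 13 of 13 complement genes (median 2.37, adjusted p = 5.4e-14, 7 up adjusted over the list alone), 11 of 12 T effector genes (median 3.39, adjusted p = 8.7e-11, 9 up) and 5 of 5 immunoglobulin genes (median 3.38, adjusted p = 0.00271, 0 up). So were 16 of 23 interstitial matrix genes (median 1.53, adjusted p = 2.4e-09, 5 up) and 10 of 16 protease and inhibitor genes (median 1.83, adjusted p = 1.5e-09, 5 up). The same held for 7 of 14 lipid-associated macrophage genes (median 0.44, adjusted p = 0.00132, 5 up and 2 down), 9 of 11 contractile genes (median 0.63 but -0.04 over mock 1, adjusted p = 0.00887, 0 up) and 6 of 12 mesenchymal transition genes (median 0.57, adjusted p = 0.0219, 1 up and 1 down, Tgfb2 at 51.2 against 107 ± 11.9). With an estimated correlation the adjusted p of these 8 lists ran from 0.597 for complement to 0.836 for contractile genes. With the version term, proteases and inhibitors, lipid-associated macrophage, immunoglobulin, contractile and mesenchymal transition genes did not pass (adjusted p from 0.120 to 0.801). Over mock 1 alone the medians of the other 7 were lower for most, at 1.34 for complement, 1.55 for T effector, 0.75 for immunoglobulin, 0.77 for matrix, 0.74 for protease, 0.60 for lipid-associated macrophage and 0.47 for mesenchymal transition genes. The 7 matrix members that were not out-of-class had a median of -0.02. The other 24 endothelial lists, among them arterial, venous, tip cell, junction, leukocyte adhesion, MHC class I and interferon-stimulated genes, did not pass.

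Sub-clusters of the endothelium were named from fixed markers, with at least 1 of them among the 10 leading genes. Arterial endothelial cells were 14.1% of ligated endothelial cells (582 of 4138) and 13.5% ± 1.74 of mock ones (n = 3), within the mock range of 11.5 to 14.7%, but above every mock library at a doubled resolution (16.0% against at most 14.9%) and with naming by score alone (15.6% against at most 15.2%). Venous cells were 5.82% (5.13 to 6.58%) against 8.68% ± 5.25, with 2.66% in mock 1 and 12.4% in mock 3. The venous sub-cluster with 539 cells of mock 2 and 822 of mock 3 had Selp alone of the venous markers among its leading genes, beside the arterial marker Vegfc. At a doubled resolution the venous share was 5.68% against 3.00% ± 0.313 and at a halved one 5.58% against 0.687% ± 0.673, so its direction turned. Sub-clusters left unnamed held 80.1% against 77.9% ± 6.99, and the sub-clusters largely followed the libraries. Named by score alone, without a check of leading genes, 1 capillary group held 0.217% of ligated, 78.4% of mock 1, 0.0198% of mock 2 and 0% of mock 3 cells.

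Mural cells of the ligated library stood apart in fewer genes than those of mock 1 did, by unadjusted p. In every other tested class the ligated library stood apart in more genes than mock 1, though by little in endothelial cells. A cluster led by Kcnj8 held 362 ligated and 132, 194 and 281 mock cells, and one led by Tagln 208 and 135, 140 and 202. Class sums thus mixed these clusters in different proportions. Gpx3 (ENSMUSG00000018339, chromosome 11, 54902453 to 54910377), an extracellular glutathione peroxidase, was at 151 CPM against 22.7 ± 5.77, and Rgs16, a regulator of G protein signalling, at 38.2 against 5.83 ± 1.53. Serpine2 was at 564 against 214 ± 27.5, Mmp11, the metalloproteinase stromelysin 3, at 51.2 against 20.8 ± 1.13, and Ppp1r15a, a phosphatase subunit of the stress response, at 120 against 45.0 ± 4.14. Lower in the ligated library were Scaf1 (12.1 against 44.2 ± 2.04), the metalloproteinase Adam9 (17.1 against 51.3 ± 2.40), the adhesion molecule Mcam (99.2 against 267 ± 43.3), the neurotrophin Ntf3 (53.9 against 107 ± 15.1) and the endothelial receptor gene Kdr (64.7 against 187 ± 33.5). Over mock 1 alone the log2 ratio of Gpx3 was 2.69. By edgeR 0 of 11543 genes passed, with 576 at an unadjusted p under 0.05, and DESeq2 called 1. In mural cells 700 passed with the version term and 1967 without mock 1. Mock 1 set against the other 3 libraries gave 1118 genes at the unadjusted level.

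In mural cells, the protease and inhibitor list (median 0.73, 6 of 13 members above the mock range, adjusted p = 5.6e-05, 2 up adjusted over the list alone) passed camera. It did not pass with an estimated correlation (adjusted p = 0.673), and its median over mock 1 was -0.15. Ribosomal protein genes (median 0.38, 22 of 26 above, adjusted p = 2.2e-06) and immediate early genes (median 0.22, adjusted p = 0.00284) passed with 0 members adjusted over the list alone, each with an adjusted p of 0.681 with an estimated correlation, and heat shock genes did too (median 0.40, adjusted p = 0.0114, and adjusted p = 0.714 with an estimated correlation). BMP pathway genes lay lower (median -0.70, 8 of 13 below, adjusted p = 0.0207), as did tip cell genes (median -0.58, adjusted p = 0.00455, 3 down adjusted over the list alone), stromal growth factors (median -0.35, adjusted p = 0.0207) and capillary genes (median -0.82, adjusted p = 4.8e-05), each with an adjusted p of 0.580 with an estimated correlation. Endothelial junction genes (median -0.53, adjusted p = 0.0207) and arterial genes (median -1.12, adjusted p = 0.0284) had an adjusted p of 0.681 with an estimated correlation, and basement membrane genes (median -0.51, adjusted p = 0.0209) one of 0.714. Over mock 1 alone the medians of the junction and arterial lists were 0.12 and 0.20, and both turned direction with the version term, as heat shock did, with a median of -0.05 over mock 1. The medians of the others over mock 1 were 0.54 for ribosomal, 0.19 for immediate early, -0.71 for BMP, -0.24 for tip cell, -0.54 for growth factor, -0.74 for capillary and -0.66 for basement membrane genes. Except for the 3 tip cell members, none of these 7 lower lists had a member passing adjusted over the list alone, by edgeR. RNA of endothelial cells in the droplets, or doublets with them, were not tested as a source of the vessel genes, Kdr included.

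Out-of-class transcripts were present in mural cells as well. They made up 5 of 9 complement genes (median 1.84, adjusted p = 5e-08, 0 adjusted over the list alone), 9 of 10 T effector genes (median 1.62, adjusted p = 2.2e-06, 0) and 12 of 13 salivary secretory genes (median 0.08, adjusted p = 0.0207, 0). With an estimated correlation the adjusted p was 0.580, 0.580 and 0.714. Lipid-associated macrophage genes (median 0.40, adjusted p = 0.0207, 2 up adjusted over the list alone, and adjusted p = 0.681 with an estimated correlation) included 3 of 13 such members. Over mock 1 the medians of these 4 lists were 1.74, 2.95, 3.25 and 0.27. Without mock 1 the salivary (adjusted p = 0.862), basement membrane (adjusted p = 0.325) and BMP lists (adjusted p = 0.181) did not pass. Without mock 3 the junction, arterial, growth factor and heat shock lists did not (adjusted p from 0.0672 to 0.107). With the version term, proteases and inhibitors, immediate early, lipid-associated macrophage and growth factor genes did not (adjusted p from 0.208 to 0.528). The other 18 mural lists, contractile genes among them, did not pass.

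The macrophage or monocyte class of the ligated library carried fewer monocyte transcripts as a whole, and its cells lay in the same 2 clusters in other proportions. A cluster led by C1qa, C1qc and C1qb held 409 ligated and 33, 94 and 118 mock cells, and one led by H2-Eb1, H2-Aa and Cd74 held 224 and 41, 204 and 270, so that the sums mix the 2 in different proportions. Plac8 (ENSMUSG00000029322, chromosome 5, 100553725 to 100572245) stood at 45.1 CPM against 260 ± 121 and Ifitm6 at 8.31 against 28.5 ± 10.6. Of the monocyte list 10 of 12 members lay below the mock range (median -1.66, and -2.36 over mock 1, where Plac8 was at -3.12). Of the T effector list 8 of 12 lay above (median 1.38), including Cxcr3, the receptor for Cxcl9, at 49.2 against 11.5 ± 2.53. Lymphocyte transcripts of other kinds lay higher in the class too. A set of 48 markers of T or NK cells outside that list summed to 5963 CPM in the ligated library against 3308, 3293 and 3667, and to 10285 against 3432, 3805 and 4057 in the cluster led by H2-Eb1, which scored 2.29 for NK or ILC1 beside 2.72 for macrophage markers. Within single clusters, looked at after seeing the data and with no test, the median of the monocyte list was -1.54 in the H2-Eb1 cluster but 0.40 in the C1qa cluster (-2.06 over mock 1), and that of the T effector list 2.11 and 1.86. By edgeR 0 of 10384 genes passed, with 1173 at an unadjusted p under 0.05, and DESeq2 called 153. In macrophages 757 passed with the version term, without mock 1 2853, without mock 3 2 and without the low count filter 247. The monocyte list (adjusted p = 6e-05, 5 down adjusted over the list alone) and the T effector list (adjusted p = 3e-07, 5 up adjusted over the list alone) passed camera, each with an adjusted p of 0.495 with an estimated correlation. The T effector median over mock 1 was 1.28.

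Several lists of vessel and basement membrane genes lay lower in macrophages of the ligated library, and fibroblast transcripts higher. Endothelial cells were a smaller share of the ligated library than of the mock libraries, in some of which doublets remain. Whether the vessel transcripts came from RNA of endothelial cells in the droplets or from doublets was not tested. This also applies to genes that were not out-of-class. The lipid phosphatases Plpp3 (49.8 against 293 ± 32.0 CPM) and Plpp1 (28.2 against 213 ± 43.7), the ubiquitin ligase Hecw2 (2.91 against 36.3 ± 7.44) and Fabp4 (116 against 1269 ± 524) were lower, and Col1a2 (27.4 against 1.72 ± 0.182) and Mgp (197 against 11.8 ± 7.77), both out-of-class, higher. The capillary (median -1.67, adjusted p = 4.5e-08, 8 down adjusted over the list alone), junction (median -1.54, adjusted p = 1.2e-06, 6 down), basement membrane (median -1.20, adjusted p = 9.1e-06, 4 down), tip cell (median -1.41, adjusted p = 4.3e-05, 2 down), arterial (median -1.34, adjusted p = 0.000187, 1 down) and BMP lists (median -1.99, adjusted p = 2.4e-05, 4 down) passed camera. Interstitial matrix genes, 10 of 12 of them out-of-class, also passed (median 1.18, adjusted p = 1.6e-05, 4 up), as did naive lymphocyte genes (median -0.90, adjusted p = 0.0395, 2 down). Each of these 8 lists had an adjusted p of 0.495 with an estimated correlation. Out-of-class were 0 of 14 capillary, 2 of 11 junction, 8 of 11 basement membrane, 3 of 9 tip cell, 4 of 9 arterial, 2 of 6 BMP and 1 of 7 naive lymphocyte genes. In the order given the medians of the 8 lists over mock 1 were -1.56, -0.91, -1.48, -1.55, -2.19, -1.40, 1.07 and -1.22. Salivary secretory genes, all 12 out-of-class, lay lower (median -1.60, adjusted p = 0.00164, 0 adjusted over the list alone, and adjusted p = 0.588 with an estimated correlation), Dcpp2 for instance at 7.06 against 74.2 ± 50.7, with a median of -0.33 over mock 1. The BMP and naive lymphocyte lists did not pass without mock 1 (adjusted p = 0.0672 and 0.191), and the matrix list did not with the version term (adjusted p = 0.580), where the salivary list turned direction. The other 23 lists, resident macrophage and lipid-associated macrophage genes among them, did not pass.

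T cells of the ligated library, taken as 1 class, carried more effector and fewer naive lymphocyte transcripts. The class sums mixed 3 clusters in different proportions. One led by Cd8b1 held 749 ligated and 72, 122 and 162 mock cells, one led by Cd3e, which scored 3.67 for NK or ILC1 and 2.52 for T cell markers, 614 and 68, 73 and 131, and one led by Cd163l1 held 82 and 18, 59 and 57. Gzmk (ENSMUSG00000042385, chromosome 13, 113171608 to 113225908), a granzyme, stood at 101 CPM against 24.9 ± 4.24, Nkg7, a cytotoxic granule protein, at 2334 against 1014 ± 75.7, the chemokine Ccl5 at 9509 against 4532 ± 585 and the inhibitory receptor Pdcd1 at 40.5 against 16.1 ± 1.95. S1pr1, the receptor that guides lymphocytes out of tissue, stood at 33.1 against 81.8 ± 14.1, and the transcription factors Tcf7 and Lef1 at 37.3 against 87.0 ± 17.3 and 25.1 against 61.2 ± 13.7. Of the effector list 9 of 13 members lay above the mock range (median 0.75, and 0.85 over mock 1), and of the naive list 8 of 9 lay below (median -1.21, and -1.28 over mock 1, where Gzmk was at 1.76, Nkg7 at 1.10 and Tcf7 at -1.45). The effector list (adjusted p = 1.3e-06, 5 up adjusted over the list alone) and the naive list (adjusted p = 0.000242, 4 down adjusted over the list alone) passed camera, each with an adjusted p of 0.413 with an estimated correlation. Within single clusters, looked at after seeing the data and with no test, the effector median was 1.31 in the Cd8b1 cluster and 0.22 in the Cd3e cluster, and the naive median -1.28 and -0.62. By edgeR 0 of 10449 genes passed, with 1191 at an unadjusted p under 0.05, and DESeq2 called 139. In T cells 748 passed with the version term, without mock 1 4350, without mock 2 2, without mock 3 1, and without the low count filter 150.

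Also in T cells, Tnni1, a troponin of slow muscle that leads an NK cluster here as well, stood at 55.1 CPM against 10.1 ± 1.14. Ifi27l2a, induced by interferon, stood at 972 against 382 ± 75.2 and the heat shock gene Hspa1b at 38.3 against 11.1 ± 2.07. Interferon-stimulated genes (median 0.35, 14 of 24 above, adjusted p = 0.00881, 1 up adjusted over the list alone) passed, with an adjusted p of 0.413 with an estimated correlation and a median of 0.31 over mock 1. Heat shock (median 0.51, adjusted p = 0.0226, 1 up and 1 down) and immediate early genes (median 0.27, adjusted p = 0.0168, 0) passed too, with adjusted p = 0.648 and 0.678 with an estimated correlation. Over mock 1 their medians were 0.16 and -0.26. With the version term camera's direction, set against the other genes, turned for both. Neither passed without mock 2 (adjusted p = 0.0596 and 0.0600), and immediate early genes did not without mock 3 (adjusted p = 0.0523).

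Fibroblast transcripts lay higher in T cells of the ligated library, among them Mgp at 209 CPM against 6.79 ± 3.45, Col1a2 at 29.4 against 0.511 ± 0.483, Apod at 41.4 against 2.44 ± 1.49 and the proteoglycan Bgn at 37.9 against 2.57 ± 1.51, all out-of-class. Out-of-class transcripts made up all 9 interstitial matrix genes (median 4.00, adjusted p = 2.1e-17, 7 up adjusted over the list alone), all 6 complement genes (median 3.76, adjusted p = 1.1e-14, 6 up), all 7 MHC class II genes (median 1.12, adjusted p = 0.00264, 1 up) and 6 of 13 lipid-associated macrophage genes (median 0.61, adjusted p = 0.00133, 5 up and 2 down). Lower lay 9 lists of vessel, signalling and basement membrane genes. As in macrophages, RNA of endothelial cells in the droplets or doublets with them were not tested as a source. These were capillary genes (median -2.03, adjusted p = 1.5e-07, 9 down and 1 up, Fabp4 at 79.5 against 896 ± 294), BMP pathway (median -1.71, adjusted p = 2.4e-06, 4 down), junction (median -1.29, adjusted p = 2.6e-05, 5 down), growth factors (median -1.78, adjusted p = 0.00157, 4 down), tip cell (median -1.22, adjusted p = 0.00336, 2 down), arterial (median -1.26, adjusted p = 0.00798, 1 down), leukocyte adhesion (median -1.18, adjusted p = 0.00798, 3 down), basement membrane (median -0.75, adjusted p = 0.00936, 0) and venous genes (median -1.34, adjusted p = 0.0147, 1 down). Mesenchymal transition genes lay higher (median 0.19, adjusted p = 0.0445, 1 up). With an estimated correlation the adjusted p of these 14 lists ran from 0.413 to 0.587. Over mock 1 the medians were 2.80 for matrix, 2.23 for complement, 0.45 for MHC class II and 0.38 for lipid-associated macrophage genes. Out-of-class were 9 of 12 capillary, 7 of 9 BMP, 7 of 11 junction, 4 of 6 growth factor, 6 of 8 tip cell, 8 of 9 arterial, 2 of 5 leukocyte adhesion, 10 of 10 basement membrane and 5 of 7 venous genes. For these 9 lists, in the order given, the medians over mock 1 were -1.41, -1.44, -0.75, -1.15, -1.65, -0.30, -0.97, -0.83 and -1.70, and for mesenchymal transition genes 0.18. Without mock 1 the tip cell, basement membrane, venous and mesenchymal transition lists did not pass (adjusted p from 0.0871 to 0.234), and with the version term the lipid-associated macrophage, arterial and mesenchymal transition lists did not (adjusted p from 0.0507 to 0.446). Mesenchymal transition genes also did not pass without mock 2 (adjusted p = 0.0991) or mock 3 (adjusted p = 0.0515). The other 13 lists, cell cycle and MHC class I genes among them, did not pass.

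NK or ILC1 cells of the ligated library also carried fewer naive lymphocyte transcripts, with 6 of 8 members below the mock range (median -1.09, and -0.83 over mock 1). Tcf7 stood at 7.53 CPM against 31.1 ± 8.14, a log2 ratio of -2.28 over mock 1. Interferon-stimulated genes lay higher (median 0.37, and 0.34 over mock 1, 14 of 24 above), such as the interferon regulator Irf7 at 66.1 against 33.8 ± 4.28. The naive list (adjusted p = 0.00259, 1 down adjusted over the list alone, and adjusted p = 0.387 with an estimated correlation) and the interferon list (adjusted p = 0.000177, 0 adjusted over the list alone, and adjusted p = 0.336 with an estimated correlation) passed camera. By edgeR 0 of 12220 genes passed, with 716 at an unadjusted p under 0.05, and DESeq2 called 52. In NK or ILC1 cells 1643 passed with the version term and 7254 without mock 1. Immediate early (median 0.39, adjusted p = 0.00976, 0, and adjusted p = 0.661 with an estimated correlation) and heat shock genes (median 0.41, adjusted p = 0.0430, 0, and adjusted p = 0.705 with an estimated correlation) had medians of -0.08 and -0.01 over mock 1 and turned direction with the version term, and heat shock did not pass without mock 2 (adjusted p = 0.0763).

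The 5 genes of smallest p in NK or ILC1 cells were all out-of-class, namely Mgp (184 CPM against 3.94 ± 0.920), C1qb (29.7 against 1.93 ± 0.342), Apoe (157 against 14.8 ± 2.83), H2-Aa (31.5 against 3.48 ± 0.377) and C1qa (34.0 against 1.70 ± 0.609). Out-of-class transcripts made up all 20 interstitial matrix genes (median 3.82, adjusted p = 1.1e-23, 13 up adjusted over the list alone, Col3a1 at 33.5 against 1.33 ± 0.947), all 13 complement genes (median 3.28, adjusted p = 4.3e-16, 5 up), all 10 proteases and inhibitors (median 2.10, adjusted p = 6.7e-07, 3 up), all 13 basement membrane genes (median 1.01, adjusted p = 1.3e-05, 0) and all 10 contractile genes (median 1.44, adjusted p = 0.000410, 0). The same held for all 6 venous (median 1.31, adjusted p = 1.3e-05, 1 up) and all 7 arterial genes (median 0.99, adjusted p = 0.0477, 0). It held for 7 of 8 MHC class II genes (median 1.02, adjusted p = 1.4e-05, 4 up), 8 of 10 homeostatic chemokines (median 1.64, adjusted p = 0.000128, 2 up), 8 of 14 lipid-associated macrophage genes (median 0.54, adjusted p = 2.7e-05, 3 up and 1 down) and 3 of 5 leukocyte adhesion genes (median 0.48, adjusted p = 0.00976, 0). Salivary secretory genes, 12 of 13 of this kind, lay lower (median -0.95, adjusted p = 0.000116, 4 down, Dcpp3 at 2.39 against 53.0 ± 10.7), with a median of 0.10 over mock 1. With an estimated correlation the adjusted p of these 12 lists ran from 0.336 to 0.607. The other 11 had medians over mock 1, in the order given, of 1.55, 1.31, 0.69, 0.26, 0.34, 0.87, 0.34, 1.20, 0.96, 0.17 and 0.22. Without mock 1 the venous, leukocyte adhesion and arterial lists did not pass (adjusted p from 0.0576 to 0.193), and with the version term the protease, basement membrane, contractile, leukocyte adhesion, salivary and arterial lists did not (adjusted p from 0.0646 to 0.966). The arterial list also did not pass without mock 2 (adjusted p = 0.259). The other 18 lists, T effector and cell cycle genes among them, did not pass.

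Fibroblasts and endothelial cells were compared with a class by surgery term, which sets the difference between the classes in 1 ligated library against that in the mock libraries. With no second ligated library it cannot tell an effect of ligation from a property of that library. The term passed an adjusted p of 0.05 for 554 of 15221 genes, with 233 higher and 321 lower in fibroblasts relative to endothelial cells, and 2903 at an unadjusted p under 0.05. Of the 321, 179 were out-of-class in endothelial cells. Genes named here are members of the fixed lists, were not out-of-class in either class and were picked after their values were seen. Col8a1 stood at 508 CPM in ligated fibroblasts against 44.4, 18.5 and 21.7 in mock ones, and at 46.2 against 33.7, 54.4 and 60.5 in endothelial cells (difference of log2 fold changes 4.37 ± 0.59 SE, adjusted p = 0.00742). Bmp6 differed by 3.79 ± 0.31 (adjusted p = 0.00137), with a log2 fold change of 0.55 in fibroblasts and -3.15 in endothelial cells. Vegfc, a growth factor of lymphatic vessels, differed by 2.46 ± 0.28 (adjusted p = 0.00450), the guidance receptor Unc5b by 1.85 ± 0.30 (adjusted p = 0.0167), the adhesion molecule Icam1 by 1.79 ± 0.22 (adjusted p = 0.00538) and Serpine2 by 1.53 ± 0.17 (adjusted p = 0.00400). Lower in fibroblasts relative to endothelial cells were Cd34, a surface sialomucin (-2.62 ± 0.20, adjusted p = 0.00115, with 156 CPM against 736, 559 and 523 in fibroblasts and 1014 against 770, 570 and 556 in endothelial cells), and Ntf3 (-1.25 ± 0.20, adjusted p = 0.0149). In endothelial cells Vegfc was at 53.6 CPM in the ligated library, 38.8 in mock 1 and 150 and 160 in mock 2 and 3. The count was 4189 without mock 1 (2283 higher, 1906 lower), 247 without mock 2 (79 and 168), 225 without mock 3 (73 and 152) and 384 of 11931 with out-of-class genes left out (196 and 188), so the side with more genes was not stable. With a class by version term, chosen after seeing the data, the count was 2065 (1100 and 965), with 1 residual degree of freedom and the spread taken from mock 2 against mock 3. There the estimate sets the ligated library against mock 1 alone. In it the 8 named genes kept their direction, at 3.04 for Col8a1, 3.36 for Bmp6, 1.52 for Vegfc and 2.69 for Unc5b. The values were 1.53 for Icam1, 1.62 for Serpine2, -2.65 for Cd34 and -1.16 for Ntf3. The fit had a term for each of the 4 libraries, so the classes were compared within libraries, of which 1 was ligated.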

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

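Among the tests below, those of the software version, of the depletion, of doublet calls and of the ratio between lymphocyte classes were chosen after the result they bear on was seen. The tests of dilution in the endothelium and of doublets with fibroblasts were set before theirs was seen.

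Fibroblasts and endothelial cells of the 1 ligated library differed in another way than those of the mock libraries for 554 genes, by the test of the difference itself, which cannot establish that the effect of ligation differs. Among list members chosen after their values were seen, the log2 fold change in fibroblasts exceeded that in endothelial cells by 4.37 for Col8a1, 3.79 for Bmp6, 2.46 for Vegfc, 1.85 for Unc5b, 1.79 for Icam1 and 1.53 for Serpine2. For Cd34 and Ntf3 the difference was -2.62 and -1.25. The lower Vegfc in endothelial cells was seen only against mock 2 and 3 (150 and 160 CPM), since the ligated library had 53.6 and mock 1, of its version, 38.8. The count ran from 225 to 4189 with 1 mock library left out and was 384 without out-of-class genes and 2065 with a class by version term.

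Fibroblasts, T cells, NK or ILC1 cells, macrophages and glia made up more of the ligated library than of the mock libraries, and endothelial cells less. The tables argue against the software version as the whole cause, since mock 1, which shares the version of the ligated library, covered a median of 0.0194 of the gap from mock 2 and 3 to the ligated library over these 6 classes (range -0.792 to 0.225). For fibroblasts they also argue against cells left by the depletion, since fibroblasts among stromal cells alone stood at 2.76 times the mock mean. Within stromal or immune cells, glia and T cells also lay above every mock library and endothelial cells below. NK or ILC1 cells and macrophages lay within the mock range of the immune cells, which bears on the mix of immune cells only. Epithelial and erythroid cells left were 2.83 and 0.366% of all ligated cells, against means of 6.56 and 1.65% in the mock libraries. Leaving them out could not close the gap of NK or ILC1 cells, 26.0% against 12.1%, or of macrophages, 5.03% against 2.64%. These values, for which no bound was set, argue against cells left by the depletion here as well. Doublet calls are argued against, since with all doublets kept the median size of the change was 0.978 of that reported. Most of these values were already known when the bounds were written, so they are weak evidence against an explanation and establish none. What stays open is any other effect of the depletion, a difference in dissociation of this 1 library, and the ligation itself, which 1 ligated library cannot test.

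Interstitial matrix genes lay higher in ligated fibroblasts and capillary genes lower in ligated endothelial cells. Over mock 1 alone the median of the matrix list was 0.379 of its pooled value, between the bounds set for and against the software version. Version and ligation therefore cannot be told apart for this list, with a single library of each group in that version. Nor can a different mix of fibroblast clusters, since the cluster led by Spp1 held 1171 ligated and 70, 35 and 57 mock cells. For the capillary list the ratio was 1.04, and genes of the list thus lay as low against the mock library of the same version, which argues against the version. Mock 1 had another feature list, so other differences of processing are not covered. Dilution by RNA of other cells would lower all endothelial markers alike, and the 44 markers outside the list had a median log2 fold change of -0.02 (quartiles -0.33 and 0.23), 0.0207 of that of the list. A change in capillary cells after ligation therefore remains a hypothesis beside a different mix of sub-types captured, and both may hold.

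Fibroblast transcripts lay higher in NK or ILC1, T and macrophage cells of the ligated library, where 46 fibroblast markers summed to 279, 309 and 390 CPM against at most 58.8, 73.1 and 213 in a mock library. In endothelial cells the sum was 620 CPM against 934, 375 and 336 in mock 1, 2 and 3, and in mural cells 1996 against 2163, 1823 and 1833. By this sum these classes are exceptions. In endothelial cells the sum is not a clean measure, since it holds Col15a1, a leading gene of an endothelial sub-cluster with 2090 mock 1 cells. Out-of-class fibroblast transcripts such as Col3a1 lay higher in ligated endothelial cells, as given above. Doublets with fibroblasts are argued against, since the 1% of ligated NK or ILC1 cells with the most such UMIs held 5.52% of them, and 76.2% of these cells had at least 1 against 15.4 to 30.3% in the mock libraries. Free RNA in the droplets is a candidate explanation: over 25 markers the ratio of T to NK or ILC1 levels had a median of 1.10 and a median absolute deviation of 0.0916 on the log2 scale, as 1 source would give. The bound for that test was written after such values had been seen, and the larger fibroblast share of the ligated library, with whatever the ligation does, stays open as the origin of such RNA.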

How the results depend on the processing

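No paired analysis was possible because the ligated and mock libraries share only the number 1. No class had a gene past the threshold in the reported fit, and the counts moved with the tool and the spread used; the cause was not tested. DESeq2 called 233 genes in endothelial cells, 282 in fibroblasts, 153 in macrophages or monocytes, 1 in mural cells, 139 in T cells and 52 in NK or ILC1 cells. With no low count filter, 23 passed in fibroblasts, 247 in macrophages, 150 in T cells and 1 in NK or ILC1 cells. With sums thinned to the smallest, 1 passed in fibroblasts, and with each library clustered on its own, 1 in T cells. Leaving out each mock library in turn gave 0 to 8939 genes in endothelial cells, 0 to 7052 in fibroblasts, 0 to 2853 in macrophages, 0 to 1967 in mural, 1 to 4350 in T and 0 to 7254 in NK or ILC1 cells, and 225 to 4189 for the difference between fibroblasts and endothelial cells. The highest count came each time without mock 1, where mock 2 and 3 alone give the spread.

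Chosen after seeing the data were the Cell Ranger version as a term, genes with short introns, doublets by score rank, sub-cluster naming by score alone and, for the difference between fibroblasts and endothelial cells, leaving out out-of-class genes and a class by version term, with which 2065 genes passed. List medians within single clusters were also added then; that of the monocyte list in macrophages, -1.66 over the class, was -1.54 in 1 cluster and 0.40 in the other, and the cause was not tested. With the version term, 5203 genes passed in endothelial cells, 3306 in fibroblasts, 757 in macrophages, 700 in mural, 748 in T and 1643 in NK or ILC1 cells. Among genes with short introns, 13 passed in fibroblasts, 1 in T and 5 in NK or ILC1 cells. With the version term the direction turned, each at an adjusted p above 0.05, for proteases and inhibitors in fibroblasts (0.992), salivary genes in macrophages (0.789), arterial (0.788), junction (0.974) and heat shock genes (0.974) in mural cells, immediate early (0.511) and heat shock genes (0.940) in T cells, and the same lists in NK or ILC1 cells (0.966 and 0.353); the cause was not tested.

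With an estimated correlation, and with fry, 0 lists passed in each of the 6 classes, against 12 in endothelial cells, 13 in fibroblasts, 11 in macrophages, 15 in mural, 19 in T and 16 in NK or ILC1 cells as reported. Shares, as ligated minus mock in percentage points, moved by more than 1 SD of the mock libraries in these cases, with the direction kept and the cause not tested. With the stricter cell filter they were, of all cells, -29.7 for endothelial cells, 5.56 for fibroblasts, 1.79 for glia, 9.87 for T cells, 16.6 for NK or ILC1 cells and -1.44 for erythroid cells, of stromal cells -21.8 for endothelial cells, 15.2 for fibroblasts and 4.10 for glia, and of immune cells -4.08 for ILC2. With the looser one they were 4.97 for fibroblasts and 7.94 for T cells of all cells, and 9.87 for T cells and -3.65 for ILC2 of immune cells. With doublets kept they were 5.22 for fibroblasts and 2.25 for glia of all cells, -21.3 for endothelial cells, 13.05 for fibroblasts and 4.85 for glia of stromal cells, and -3.56 for ILC2. With doublets by rank they were 4.47 for fibroblasts and 7.94 for T cells of all cells, 10.9 for fibroblasts and -17.8 for endothelial cells of stromal cells, and 9.59 for T cells and -3.37 for ILC2 of immune cells. With each library clustered on its own they were 5.04 for fibroblasts, 1.91 for glia and -6.05 for epithelial cells of all cells, and 4.00 for glia of stromal cells. With a clustering resolution of 2.0 erythroid cells were at -1.86. With each library clustered on its own no value could be given for ILC2 and erythroid cells, since in some libraries no cluster took the name. Unnamed endothelial sub-clusters went from 2.25 to 27.3 with naming by score alone and to -5.35 at the halved resolution, and venous ones from -2.85 to 2.68 at the doubled and 4.90 at the halved one; the cause was not tested.

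Of the alternatives, 99 of the counts stayed within 1.5 times and 46 did not, over 13 results. For the 86 lists that passed, 283 values stayed past the threshold in the same direction, 224 fell short of it and 9 turned. The 224 include every list with an estimated correlation and with fry, which rest on 2 residual degrees of freedom. For the 99 named genes 1241 stayed on the same side, 287 came to pass and 1 ceased to. For the 20 shares 134 stayed within 1 SD, 32 moved further and 3 turned.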

Other observations

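Glia of the ligated library, 309 cells against 23, 44 and 51 in mock 1, 2 and 3, carried more transcripts of several genes of the fixed list of Schwann cell repair genes, given as values with no test. Ngfr, the low-affinity neurotrophin receptor, stood at 162 CPM against 55.6 ± 29.1 (SD, n = 3), the transcription factor Sox2 at 117 against 34.0 ± 8.62, the filament gene Gfap at 83.8 against 48.6, 17.5 and 10.6 in mock 1, 2 and 3 (97 UMIs against 6, 3 and 2) and the growth factor Btc at 90.7 against 16.2, 0 and 0 (105 UMIs against 2, 0 and 0). In mock 1, of the version of the ligated library, Ngfr was at 89.2 and Sox2 at 24.3. Olig1 had 25 UMIs in ligated glia and 0 in each mock library, at least 3.48-fold higher against a floor of 3 counts over all mock glia (6.19 CPM). The transcription factor Jun stood at 670 CPM, beside 665 in mock 1 and 221 and 380 in mock 2 and 3, the adhesion molecule L1cam at 424 against 368 ± 77.6 and Ncam1, lower, at 494 against 857 ± 101. Shh had 0 UMIs in every library, Runx2 stood at 64.8 CPM against 34.9 in mock 2 and 0 in mock 1 and 3, and Gdnf at 10.4 against 8.11 in mock 1 and 0 in the others. Artn and Bdnf had 11 and 14 UMIs in ligated glia and 0 in mock glia, which held far fewer UMIs in all.

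Myelin genes of the same cells mostly stood lower. The myelin gene Ncmap was at 10.4 CPM against 88.2 ± 39.2, Mal at 494 against 800 ± 127 and Cnp at 501 against 683 ± 37.9. Mbp (300 against 581 ± 227), Pmp22 (821 against 1289 ± 461), Prx (6.91 against 42.3 ± 32.0) and Drp2 (9.50 against 53.2 ± 41.2) also had lower values, and Mag (18.1 against 23.4 ± 16.5) and Egr2 (6.04 against 10.7 ± 9.26) lay within 1 SD of the mock mean. Pmp2 had 0 UMIs in every library. The sums rested on 1158171 UMIs in the ligated library and 123371, 171710 and 189248 in the mock libraries.

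Other classes too small for a test included lymphatic endothelial cells, with 31 ligated cells against 7, 11 and 9, and B cells with 13 against 11, 17 and 14.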
